A study of Mus musculus with 22 samples.

How the data were processed

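ATAC-seq, in which Tn5 transposase inserts sequencing adapters into accessible DNA, was measured in 22 libraries of mouse germ cells purified by FACS. Of these, 17 came from spermatogonia collected on day 7 after tamoxifen, which activates a Cre recombinase. They were sorted by MCAM, a surface adhesion molecule, and by KIT, the receptor that marks differentiating spermatogonia. The other 5 came from later germ cells, spermatocytes or round spermatids. Groups were taken from the sample titles and marker entries. The titles separate TERT-heterozygous (control) from TERT-deleted mice, whereas the genotype entry in the labels is the same for both. For 4 of the 5 later libraries the title and the library name disagree about the cell type, so the 5 were kept as 1 group.

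The authors deposited 1 table of whole-number read counts per peak, not normalized, with 96049 peaks shared by all libraries; per the file headers it gives chromosome, start and end. Per the submitters' processing notes, FastQC, Bowtie2, SAMtools and Picard were used, and the builds mm10, GRCm38 and hg19 were named without a role. The peak caller, the rule for merging peaks, the counting tool, any Tn5 offset of the reads, and any filter on duplicate, mitochondrial or blacklisted reads were not given in the sources used here. A Tn5 offset of a few bases moves few reads in or out of peaks whose median width was 417 bp (range 200 to 3274). Duplicate reads would add to the spread of low counts. Between 48.8% and 73.9% of the nonzero counts of a library were even. The share was 49.3 to 49.9% in the 5 later libraries and 50.7 to 73.9% in control KIT-positive ones. An excess of even counts arises when both ends of a fragment are counted, and counting intervals are then too narrow. Whether peak starts count from 0 or 1 was not given, and starts were used as deposited.

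Total counts in peaks ranged from 922085 to 3358377 per library. At 3 counts, the floor used for a count of 0, this corresponds to 0.893 to 3.25 CPM (counts scaled to the size of each library). Intervals and floors cover counting error only, since reads from 1 amplified molecule are not independent. Library names of spermatogonia carry 1 number across the sorted populations, as if each number were 1 source. Nothing in the labels says that replicates came from separate mice, so p-values measure the spread between these libraries, which may be technical.

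Peaks were assigned to genes with a RefSeq gene table of assembly GRCm38.p6, using the 34632 protein-coding and lncRNA genes plus any other gene of the lists. The table gives no strand, so the planned window around transcription start sites was replaced by a gene end: within 1 kb of either annotated end of a gene. By that rule 23758 peaks (24.7%) were at a gene end, 34928 (36.4%) in a gene body and 37363 (38.9%) intergenic. A peak on a sequence for which the table holds no gene counted as intergenic. A named peak was not assigned to an exon, intron or UTR, because the table does not hold them. No genome sequence was used here.

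Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, quasi-likelihood F tests, and Benjamini-Hochberg adjustment over all peaks tested with a threshold of 0.05. The 17 spermatogonial libraries entered 1 fit with a mean per group (57289 peaks tested, 11 residual degrees of freedom). The 13 heterozygous libraries entered a separate fit for later germ cells against KIT-positive spermatogonia (73134 peaks). Contrasts were deleted minus control in each of the 3 populations, their mean, the differences of these effects between populations, the 3 differences between control populations, and later germ cells minus KIT-positive cells. Standard errors are the log2 fold change divided by the square root of F. CPM values of groups at single peaks are TMM-scaled. CPM values of the Y stretch and of other Y peaks as a sum, of the Terc peak in single libraries and of library values far from their group are scaled to total counts in peaks instead. Group values are mean ± SD. A fold against a group at 0 counts was computed against 3 counts over the whole group. If both ends of a fragment were counted, that floor is too low, and the folds given as at least a value are too high.

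Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) on 1 gene-end peak per gene, that with the highest mean count; 16252 genes had a tested gene-end peak. The 15 lists held 355 genes, all found in the gene table: undifferentiated spermatogonia, differentiating spermatogonia, meiosis, spermiogenesis, MYC targets with ribosome biogenesis, the MYC family, the p53 and DNA damage response, telomeres and telomerase, WNT targets, the GDNF, FGF and MAPK response, replication and cell cycle, and markers of Sertoli, Leydig, immune, and peritubular or endothelial cells. Adjusted p-values of lists cover all lists and contrasts of 1 kind. Shares of peaks at gene ends were compared with Fisher's exact test, and shares of counts per chromosome with exact two-sided permutation tests. The groups, tests, lists, alternatives and the naming rule were fixed before the data were examined, except for those said to have been added.

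Peaks were named by a fixed rule. For each of the 3 deletion contrasts, control KIT-positive minus MCAM-high, and later germ cells minus KIT-positive, these were the 12 highest and 12 lowest fold changes among peaks that passed the threshold, lay above the median mean log2 CPM, had groups that did not overlap, and were at a gene end or in a gene body. Where fewer than 5 passed, the 5 peaks with the smallest p were taken. Up to 4 gene-end peaks with the smallest p were taken from each list, and all peaks of the Tert locus. Some of the peaks so chosen are not reported here. The examples given in the text come from these, and peaks outside the rule are said to have been chosen after their values were seen.

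The test was tried on simulated counts with the means and depths of these libraries and 100 planted changes of each size. Of the planted 4-fold changes, 47% were called for the deletion in MCAM-high cells (51884 peaks in the fit), 31% in MCAM-medium cells (52005) and 43% in KIT-positive cells (51845). The share was 44% for control KIT-positive against MCAM-high cells (52018) and 51% for later germ cells (62317). Of the 2-fold changes, 5%, 4%, 6%, 5% and 6% were called in the same order. False calls numbered 3, 7, 2, 0 and 2 in that order. They arose beside the planted changes that were called, and the adjustment allows more false calls as more peaks are called. They therefore do not give the number of false calls among the 5 and 2 peaks called for deletion in MCAM-medium and KIT-positive cells. DESeq2 called 42% of the 4-fold and 2% of the 2-fold changes for the deletion in MCAM-high cells.

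Alternatives chosen beforehand were DESeq2 size factors, total counts without TMM, loess offsets, no filter, a filter of at least 30 counts in at least 2 libraries, the DESeq2 1.42.0 Wald test, glmTreat against a log2 fold change of 0.5, omission of X and Y, fits of only the groups compared, a replicate block, and omission of each library in turn. For lists they were an estimated correlation, fry, all peaks nearest a gene within 50 kb, and the block; for gene-end shares, a window of 2.5 kb; for chromosome shares, tested peaks only. Alternatives added after the data were seen left out unplaced contigs with X and Y, left out 2 control libraries or exchanged their labels, or left out the 3 deleted libraries numbered 1. The differences between deleted populations were also added. Figures were drawn with matplotlib 3.10.9.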

Results

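Open chromatin was profiled by ATAC-seq in mouse male germ cells to ask how acute loss of TERT, the catalytic subunit of telomerase, changes it in spermatogonia. Spermatogonia were sorted 7 days after tamoxifen into MCAM-high KIT-negative and MCAM-medium KIT-negative cells, both undifferentiated per the labels, and KIT-positive cells, which are differentiating. Control (TERT-heterozygous) libraries numbered 3, 2 and 3 in these populations, and TERT-deleted libraries 3 in each. A further 5 heterozygous libraries came from spermatocytes or round spermatids. Total counts in peaks were 2212132 ± 453808 (SD, n = 3) in control MCAM-high cells, 1884097 ± 380822 (n = 2) in control MCAM-medium cells and 1411210 ± 527803 (n = 3) in control KIT-positive cells. The deleted libraries held 1245977 ± 201514, 1376251 ± 166140 and 1444067 ± 329313 counts (n = 3 each), and the later germ cells 2028283 ± 765987 (n = 5).

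The deleted gene was examined first. Tert had 1 tested peak within its bounds or 10 kb around them (chromosome 13, 73626569 to 73627516, GRCm38), which overlapped the annotated start coordinate of the gene at 73626911. Its signal was 22.7 ± 0.929 CPM in control and 19.0 ± 1.97 CPM in deleted MCAM-high cells (SD, n = 3 each). It was 20.4 ± 0.729 (n = 2) and 20.1 ± 5.55 CPM (n = 3) in MCAM-medium cells, and 23.8 ± 8.13 and 16.4 ± 1.14 CPM (n = 3 each) in KIT-positive cells. The mean log2 fold change over the 3 populations was -0.28 ± 0.20 (SE, edgeR adjusted p = 0.976), which did not pass. Which part of Tert was deleted was not given in the sources used here, so a peak at a gene end does not check the deletion, and the genotype rests on the sample titles.

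The gene of the telomerase RNA, Terc, which provides the template for telomere repeats, carried a strong peak at its own position (chromosome 3, 96414052 to 96414936). Averaged over the 3 populations this peak fell by 1.53 on the log2 scale (SE 0.30, edgeR adjusted p = 0.00694). Per population the log2 fold change was -1.03 ± 0.49 in MCAM-high (edgeR adjusted p = 0.832), -2.17 ± 0.55 in MCAM-medium (0.408) and -1.40 ± 0.51 in KIT-positive cells (1), none of which passed. The libraries differed widely: scaled to total counts, control values were 177, 711 and 618 CPM in MCAM-high, 717 and 191 CPM in MCAM-medium, and 165, 343 and 251 CPM in KIT-positive replicates 1 to 3. Deleted replicate 1 was at 33.6, 26.4 and 24.2 CPM in the 3 populations, replicate 2 at 516, 180 and 177 CPM, and replicate 3 at 192, 99.8 and 81.5 CPM. The deleted libraries thus ran in the same order of number in each population, and the test of the mean treats all 9 as independent. The call in the mean was lost without control MCAM-medium replicate 1 (edgeR adjusted p = 0.0826), without the 3 deleted libraries numbered 1 (log2 fold change -1.07, adjusted p = 0.264) and with DESeq2 (adjusted p = 0.533).

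**Figure D1:**
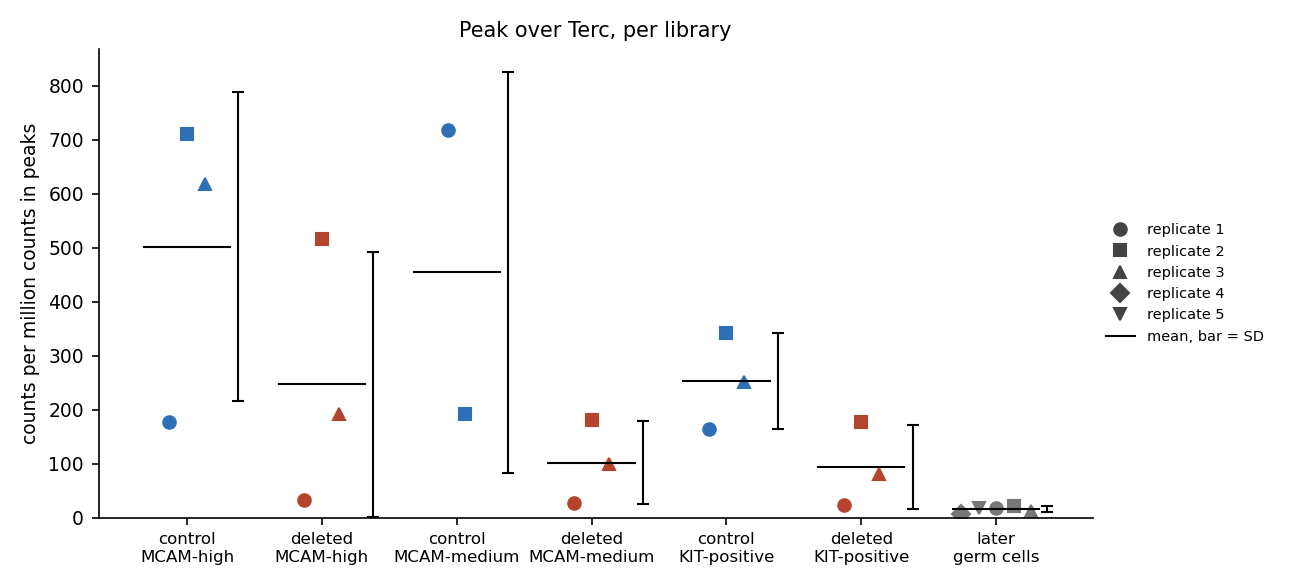
ATAC-seq signal of the Terc peak (y axis, CPM, linear from 0) in the 7 groups (x axis); each point is 1 library, with 1 marker shape per replicate number, lines are group means and bars SD. The deleted libraries numbered 1 lie between 24.2 and 33.6 CPM, under all control libraries, whereas deleted MCAM-high replicate 2 reaches 516 CPM.

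TERT-deleted MCAM-high cells differed from control MCAM-high cells at a small set of sites. The mice differ along with the genotype. A difference between the mice thus cannot be told from an effect of deletion at any site called here or in the other populations. All 28 called were higher in the deleted cells, whereas with no filter on low counts 70 were higher and 31 lower. The most pronounced lay in 1 stretch of the Y chromosome that holds peaks nearest to Gm20830, Gm20873 and Gm20914, predicted genes of multicopy Y families. A peak inside Rest, which encodes a repressor of neuronal genes, rose from 6.62 ± 1.74 to 30.5 ± 5.53 CPM (SD, n = 3 each). A peak inside nonagouti (symbol a), a coat colour gene, rose from 2.23 ± 1.57 to 22.5 ± 11.8 CPM, and a peak inside Copg2, which encodes a coatomer subunit, from 6.47 ± 0.590 to 27.6 ± 5.51 CPM. A peak at an end of 4931408C20Rik rose from 12.7 ± 5.96 to 56.2 ± 7.48 CPM.

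In all, 28 of 57289 tested peaks passed in MCAM-high cells, of which 9 were on Y, 10 on 1 unplaced contig and 9 on autosomes. The 4 peaks in or at genes that met the naming rule were the following. The 4931408C20Rik peak (chromosome 1, 26686845 to 26688325, gene end) had a log2 fold change of 2.16 ± 0.33 (SE, edgeR adjusted p = 3.46e-04). The Rest peak (chromosome 5, 77281456 to 77282624, gene body) had 2.19 ± 0.38 (0.00377), and the nonagouti peak (chromosome 2, 155020260 to 155020637, gene body) 3.29 ± 0.58 (0.00414). The Copg2 peak (chromosome 6, 30804485 to 30805754, gene body) had 2.06 ± 0.42 (0.0281). The 4931408C20Rik call held in all 6 fits that left out 1 library of either group. The Rest call was lost without control replicate 2 or deleted replicate 2 (highest adjusted p 0.0667), that of nonagouti without control replicate 2 or deleted replicate 1 (0.240), and that of Copg2 in each of the 6 fits (highest 0.351). In a fit without X, Y and unplaced contigs, added after the data were seen, only 3 of the 9 autosomal calls held, those of 4931408C20Rik, Rest and nonagouti, and Copg2 had an adjusted p of 0.0961 at the same log2 fold change. The count was 13 without control replicate 1, 16 without control replicate 2, 13 without deleted replicate 1 and 15 without deleted replicate 2. Only 7.14% of the 28 peaks were at a gene end, against 33.5% of all tested peaks (Fisher's exact test, odds ratio 0.153, 95% interval 0.0176 to 0.610, adjusted p = 0.00256 over 20 tests). This test counts neighbouring peaks as independent. The 9 peaks on Y and 10 on the contig, all classed intergenic, carried the deficit: of the 9 on autosomes 2 were at a gene end and 5 in a gene body. No gene was available for the contig, so its 10 peaks could have no other class and do not measure a deficit.

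The Y stretch spanned 5657392 to 10366704 and held 39 peaks, of which 30 were tested and 25 were higher in the mean of the 3 populations. The 8 control libraries held 113 counts there of 14638218, at most 19 in a library, and the 9 deleted libraries 3342 of 12198884, at least 104 in each. Scaled to total counts, the stretch had 7.26 ± 1.75 CPM in control and 385 ± 108 CPM in deleted MCAM-high cells (SD, n = 3 each). It had 6.04 ± 0.656 (n = 2) and 321 ± 143 CPM (n = 3) in MCAM-medium cells, and 10.8 ± 3.30 and 135 ± 43.2 CPM (n = 3 each) in KIT-positive cells. Later heterozygous germ cells were at 10.5 ± 5.01 CPM (n = 5). The highest control library, at 13.4 CPM, lay under the lowest deleted one, at 90.0 CPM. Single peaks in it had 0 counts in whole control groups: the peak at 7027473 to 7028073, nearest to Gm20830 (110355 bp away), was at least 93.5-fold higher in deleted MCAM-high cells, and the peak at 6013937 to 6014352, nearest to Gm20873 (254373 bp away), at least 36.2-fold higher. Both bounds are too high if both ends of a fragment were counted. These families share near-identical copies, so the assignment of reads among copies is uncertain.

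**Figure D2:**
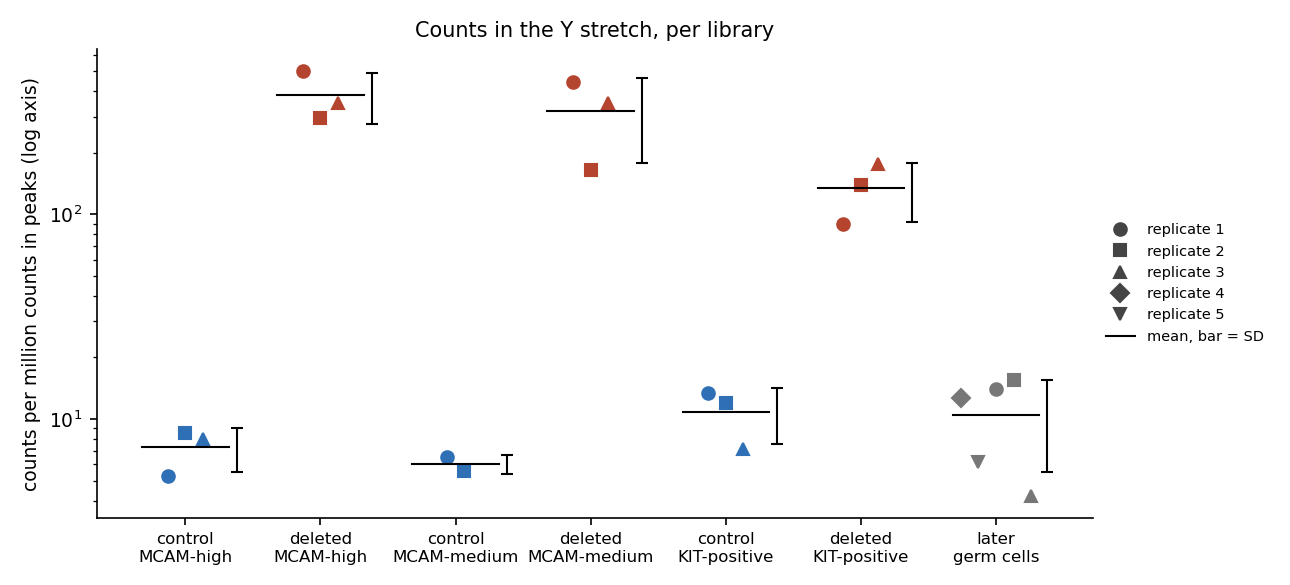
Signal of the 39 peaks in the Y stretch (y axis, CPM, log scale) in the 7 groups (x axis); each point is 1 library, with 1 marker shape per replicate number, lines are group means and bars SD. All 9 deleted libraries lie at or above 90.0 CPM, and the 8 control libraries at or under 13.4 CPM.

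In MCAM-medium cells the sites called were 5 peaks of the same Y stretch, all higher after deletion. The peak at 6786878 to 6787479, nearest to Gm20830 (128955 bp away), had 0 counts in the controls and 22.8 ± 12.5 CPM in the deleted cells (SD, n = 3), at least 27.8-fold higher (edgeR adjusted p = 8.30e-04). The peak at 6821543 to 6821982 rose from 0.633 ± 0.895 (n = 2) to 32.6 ± 19.7 CPM (n = 3; edgeR adjusted p = 8.30e-04). The count was 0 without control replicate 1, which leaves 1 control library whose spread is assumed to be that of the other groups, with 2299 peaks at an unadjusted p under 0.05. It was 3 without deleted replicate 1, 12 when only the groups compared were fitted, and 0 without X and Y.

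In KIT-positive cells 2 peaks passed. An intergenic peak on chromosome 8 (20122075 to 20122916), whose nearest protein-coding gene is 9530057J20Rik at 186745 bp, fell from 57.0 ± 15.9 to 15.3 ± 4.99 CPM (SD, n = 3 each), a log2 fold change of -1.94 ± 0.33 (SE, edgeR adjusted p = 0.0229). The Y peak at 7036708 to 7037355, nearest to Gm20830 (119590 bp away), was at 0 counts in the controls and 11.1 ± 10.2 CPM in the deleted cells, at least 13.3-fold higher (edgeR adjusted p = 0.0263). DESeq2 did not call it. The next smallest p-values, none of which passed, belonged to peaks at Gm40469 (log2 fold change -2.20 ± 0.45), 70681 bp from A530021J07Rik (4.52 ± 0.94) and in Rest (1.95 ± 0.41), each with an edgeR adjusted p of 0.200. The count was 1 without control replicate 1 or deleted replicate 2, and 0 without control replicate 3 or deleted replicate 3 (2877 and 2171 peaks at an unadjusted p under 0.05).

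Averaging the 3 populations, 59 peaks were higher and 12 lower in deleted cells, with 26 of the 71 on Y, 12 on 1 unplaced contig (1915 to 54368), 31 on autosomes and 2 on X. The 12 contig peaks had log2 fold changes of -0.14 to 0.80 in KIT-positive cells. The 10 of them called in MCAM-high cells had 1.38 to 2.06 there, values that are high by that choice. No peak passed the test of a difference between these populations. The genes named here for the mean were chosen after their values were seen. Rest rose by 1.97 ± 0.24 on the log2 scale (SE, edgeR adjusted p = 5.35e-07). A gene-end peak rose at Mfsd8, which encodes a lysosomal membrane protein (chromosome 3, 40846418 to 40847394; 0.88 ± 0.15, edgeR adjusted p = 7.39e-04). On chromosome 8, 4 of 5 called peaks between 19784468 and 20550886 were lower, among them the 9530057J20Rik-nearest peak (-1.58 ± 0.19, 5.35e-07) and a gene-end peak of Gm40469 (-1.98 ± 0.26, 5.01e-06). Calls of Rest, Mfsd8, Gm40469 and the 9530057J20Rik-nearest peak held in all 17 fits without 1 library. Each of these fits kept the other libraries of the same number, so they do not test whether the calls rest on 1 source. The test of the mean treats all 17 libraries as independent.

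The deletion effect was not shown to differ between populations. With edgeR, 0 peaks passed for KIT-positive minus MCAM-high, MCAM-medium minus MCAM-high and KIT-positive minus MCAM-medium, with 2855, 2476 and 2372 at an unadjusted p under 0.05. DESeq2 also gave 0 for each (2761, 2218 and 2370 at an unadjusted p under 0.05). Without control MCAM-medium replicate 2, 115 peaks passed for MCAM-medium minus MCAM-high.

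None of the 15 gene lists moved as a group with deletion in any of the 3 populations. With camera 0 of 45 tests passed, 1 had an unadjusted p under 0.05, and both an estimated correlation and fry gave 0. The lowest camera adjusted p was 0.597, for differentiating spermatogonia in KIT-positive cells, where the median log2 fold change was -0.17 over 16 genes. Among genes of the undifferentiated state in MCAM-high cells, Etv5, a transcription factor downstream of GDNF, was at -0.48 ± 0.22 (SE, edgeR adjusted p = 0.790), and Zbtb16, a factor of stem cell maintenance, at -0.42 ± 0.26 (0.930). The replication gene Mcm7 was at 0.65 ± 0.21 (0.508) and the synaptonemal gene Syce1 at 1.08 ± 0.36 (0.519). Adjusted over the list alone, Terc was lower in MCAM-medium cells and Pes1, a ribosome biogenesis factor, higher in KIT-positive cells, and no other member passed.

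Whether sites that changed with deletion were those that change with differentiation was asked with comparisons that share no library. Across 57289 peaks, which are not independent replicates, the deletion effect in MCAM-high cells correlated with control KIT-positive minus MCAM-medium at r = 0.150 (covariance 0.0729). Simulated groups without effects gave 0.000312 and 7.82e-05, as means of 20 simulations. The simulations drew all libraries as independent, so they hold nothing that libraries of 1 number may share. The covariance was 0.143 with loess offsets (r = 0.172) and 0.0335 over the 28590 peaks above the median mean count (r = 0.109). Of the 28 peaks higher in deleted cells, 6 were among the 3267 higher in KIT-positive cells, against 1.60 for independent lists, and 0 among the 2075 lower, against 1.01. These expected numbers count neighbouring peaks as independent, although 9 of the 28 were on Y and 10 on 1 contig. The correlation was 0.0593 without control MCAM-medium replicate 2, 0.0868 without control MCAM-high replicate 3, 0.218 without control MCAM-high replicate 1 and 0.218 without control MCAM-medium replicate 1. For the pair that shares the control MCAM-high libraries, r was 0.258 and the covariance 0.126, against 0.435 and 0.0950 from the shared controls alone, a difference in covariance of 0.0312. The 3 shared control libraries cannot be split into parts of at least 2, so no pair of separate controls could be formed for it.

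Control KIT-positive cells differed widely from MCAM-high cells. Gene-end peaks rose at replication genes, among them Mcm7, a subunit of the replicative helicase, Pcna, the sliding clamp, and Cdc6, which loads the helicase. They rose at Meioc, a meiotic RNA-binding factor, Dmrt1, a regulator of the mitosis to meiosis switch, Uhrf1, a maintenance methylation factor, and Kit itself, and at Npm1, Nme1 and Eif5a of the list of MYC targets with ribosome biogenesis. Peaks fell at Ccnd2, a D-type cyclin of undifferentiated spermatogonia, and at Nanos2, an RNA-binding protein of stem cells. Bmi1, a Polycomb gene of the same list, rose.

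In all, 9024 of 57289 peaks (15.8%) passed, 5522 higher and 3502 lower in KIT-positive cells. Under total counts without TMM the split was 4067 higher and 5005 lower (44.8% against 61.2% higher), with a median log2 fold change over all peaks of -0.22 in place of -0.05. Peaks at gene ends made up 47.5% of the higher and 22.9% of the lower sites, against 33.5% of those tested (Fisher's exact test, odds ratios 1.92, 95% interval 1.82 to 2.03, and 0.571, with 0.619 as its upper bound, with adjusted p = 3.27e-112 and 3.97e-45 over 20 tests). These p-values and the interval count peaks as independent, so they do not measure the spread between libraries. Among the largest changes, a peak in Rcan3, a regulator of calcineurin (chromosome 4, 135430199 to 135430747), rose from 1.47 ± 0.605 to 63.1 ± 24.4 CPM (SD, n = 3 each; log2 fold change 5.42 ± 0.47 SE, edgeR adjusted p = 2.11e-11). A peak in Cbfa2t3, a transcriptional corepressor (chromosome 8, 122687761 to 122688223), went from 0 to 30.6 ± 8.53 CPM, at least 65.4-fold higher (edgeR adjusted p = 6.18e-09). Peaks in Tns1 (5.62 ± 0.80), Mgat5b (5.56 ± 0.65) and Ror2 (5.47 ± 0.69) and at the ends of C1ql1 (5.40 ± 0.51) and Trim50 (5.24 ± 0.59) also rose. Among the lower sites, a peak in Nkain2 (chromosome 10, 32548599 to 32549094) was at least 20.2-fold lower, from 16.8 ± 8.69 CPM to 0, and peaks in Ahnak, Tbl1x, Plaat3, Galnt14 and Oxr1 fell by 5.41, 4.40, 4.38, 4.34 and 4.22 on the log2 scale. The calls of these peaks held in all 6 fits without 1 library, while the total was 5674 without control MCAM-high replicate 2, 5641 without control MCAM-high replicate 3 and 5054 without KIT-positive replicate 3.

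Gene-end peaks as a class leaned upward: they held 59.3 ± 4.88% of counts in control KIT-positive and 53.8 ± 1.0% in MCAM-high cells (SD, n = 3 each), and 60.1 ± 2.70% and 53.6 ± 0.847% in deleted cells. Control KIT-positive replicates 1 to 3 held 54.4, 59.2 and 64.2%, so replicate 1 lay within the control MCAM-high range (52.8 to 54.8%). The deleted ranges did not overlap (57.7 to 63.0% and 52.8 to 54.5%). Even counts ran in the same order in control KIT-positive replicates (50.7, 62.5 and 73.9%). Deleted MCAM-medium replicate 3, at 73.7% even, held 53.7% at gene ends. A link was not tested. The median log2 fold change of gene-end peaks in controls, with 1 peak per gene, was 0.19, against -0.05 for all peaks. Camera compares a list with these peaks, whereas the counts of genes that rose do not allow for the lean. Of the 27 replication and cell cycle genes measured, 16 rose and 0 fell (21 and 0 adjusted over the list alone; camera adjusted p = 7.84e-08, adjusted p = 0.249 with an estimated correlation). Log2 fold changes were 1.47 ± 0.21 for Mcm7 (SE, edgeR adjusted p = 3.21e-06), 1.28 ± 0.22 for Pcna, 1.71 ± 0.30 for Cdc6 and 1.12 ± 0.22 for Gins2. Of 16 genes of differentiating spermatogonia, 6 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.0254, adjusted p = 0.211 with an estimated correlation), with Meioc at 1.73 ± 0.29, Dmrt1 at 1.39 ± 0.25, Uhrf1 at 1.03 ± 0.23 and Kit at 0.99 ± 0.26. Of 45 MYC targets and ribosome biogenesis genes, 15 rose and 1 fell (22 and 1 adjusted over the list alone; camera adjusted p = 4.46e-04, adjusted p = 0.496 with an estimated correlation), among them Eif5a at 1.38 ± 0.22, Eif4a1 at 1.07 ± 0.22, Npm1 at 1.05 ± 0.22 and Nme1 at 1.45 ± 0.30. With loess offsets 12 were higher and 3 lower, and the list's median log2 fold change went from 0.61 to 0.30. Of the 11 MYC family genes, 4 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.0272, adjusted p = 0.390 with an estimated correlation). These were Mnt (0.74 ± 0.22), Mxd4 (0.69 ± 0.22), Mga (0.78 ± 0.25) and Mxd3 (0.73 ± 0.25), all of which encode partners of MAX that oppose MYC rather than MYC itself. Their number was 0 with loess offsets and 1 with total counts, while the list's median log2 fold change was 0.73, and 0.47 and 0.56 in those settings. The differentiating list was lost without control MCAM-high replicate 2 or KIT-positive replicate 1 (highest camera adjusted p 0.0861), and the MYC family without MCAM-high replicate 2 or KIT-positive replicate 3 (0.0564).

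**Figure D3:**
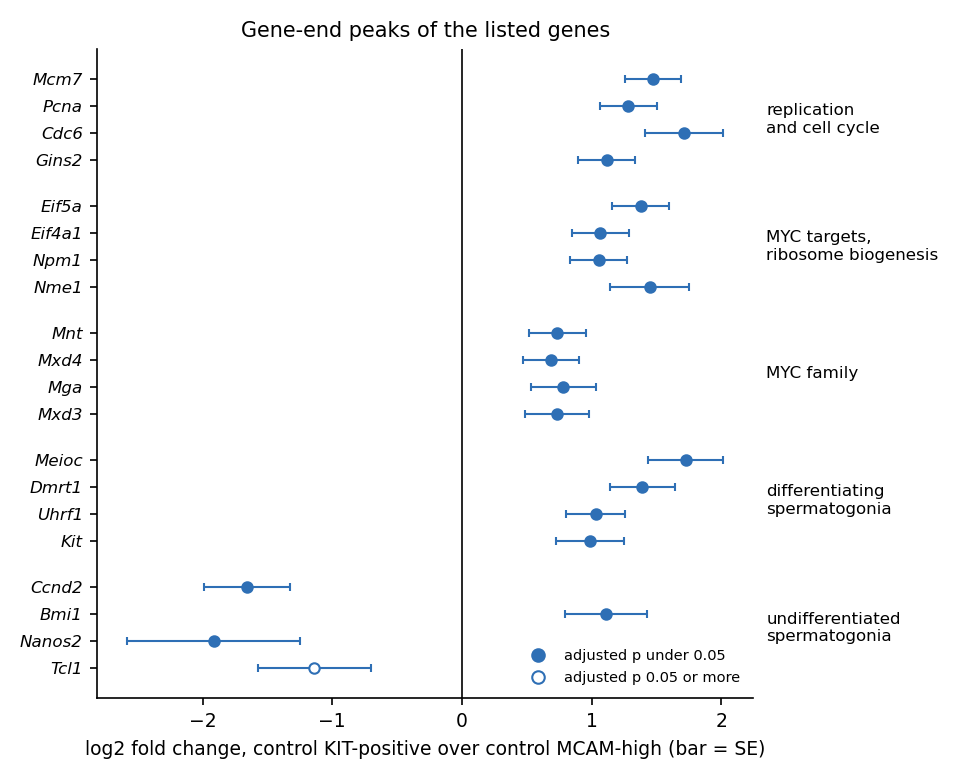
Log2 fold change of gene-end peaks in control KIT-positive over control MCAM-high cells (x axis) for 4 genes of each of 5 lists (y axis); points are estimates, bars 1 SE, and filled points have an edgeR adjusted p under 0.05. The replication genes lie between 1.12 and 1.71, Ccnd2 and Nanos2 at -1.66 and -1.91, and Tcl1 is the only open point.

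Of 31 genes of the undifferentiated state, 1 rose and 2 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.355). Ccnd2 was at -1.66 ± 0.33 (SE, edgeR adjusted p = 4.22e-04), Nanos2 at -1.91 ± 0.67 (0.0413), Bmi1 at 1.11 ± 0.32 (0.0130) and Tcl1 at -1.14 ± 0.43 (0.0648). Of 35 meiosis genes, 9 rose and 2 fell (15 and 3 adjusted over the list alone; camera adjusted p = 0.321), with Msh5 at 1.35 ± 0.25 and the spermatocyte glycolytic gene Pgk2 at -1.64 ± 0.48. Of 11 spermiogenesis genes, 2 rose, Crem (0.73 ± 0.22) and the protamine-related gene Prm3. Of 26 p53 and DNA damage genes, 5 rose, among them Mdm2 (1.34 ± 0.28), Aen (0.96 ± 0.24), Trp73 (1.46 ± 0.36) and Bbc3, and 1 fell. Of 21 telomere genes, 5 rose, among them Acd (1.23 ± 0.27), Tnks2 (1.46 ± 0.42), Gar1 (1.07 ± 0.32) and Tinf2 (0.94 ± 0.30), and 1 fell. Of 12 WNT targets, Znrf3 (1.13 ± 0.27) and Nkd1 (0.94 ± 0.28) rose and Sox17 (-0.82 ± 0.23) fell. Of 21 GDNF, FGF and MAPK response genes, Spred2 (0.98 ± 0.28) and Spred1 (0.94 ± 0.32) rose. None of these lists passed with camera (adjusted p 0.965, 0.368, 0.429, 0.846 and 0.490 in that order for spermiogenesis, p53, telomere, WNT and GDNF). With total counts 4 meiosis genes were higher and 3 lower, 4 and 2 p53 genes, and 3 and 1 telomere genes. With loess offsets these were 5 and 2, 4 and 3, and 3 and 3. Adjusted over the list alone, 3 spermiogenesis, 8 p53, 6 telomere, 2 WNT and 1 GDNF genes were higher, and 0, 1, 1, 1 and 0 lower.

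Markers of somatic cells gave little signal in this comparison. Adjusted over the list alone, 0 genes of the Sertoli (9 measured), Leydig (2), immune (3), and peritubular or endothelial (10) lists passed. Over all peaks only Acta2, a smooth muscle actin gene, rose, at 1.19 ± 0.42 (SE, edgeR adjusted p = 0.0444), and camera gave adjusted p-values of 0.429, 0.355, 0.490 and 0.269. Some of the calls above rested on single libraries. Kit and Spred2 were lost without control MCAM-high replicate 2 (edgeR adjusted p 0.0605 and 0.0807), Sox17 without replicate 3 (0.0649), and Znrf3 without KIT-positive replicate 3 (0.0939). Bmi1, Bbc3, Tnks2, Gar1 and Nkd1 were lost without control MCAM-high replicate 3 or KIT-positive replicate 3 (highest 0.231), Crem without control MCAM-high replicate 1 or KIT-positive replicate 3 (0.101), Pgk2 without KIT-positive replicate 2 or 3 (0.136), and Prm3 without KIT-positive replicate 2 (0.0619). Nanos2, Mxd4, Mga, Mnt, Mxd3, Tinf2, Spred1 and Acta2 were each lost in 3 or 4 of the 6 fits. Loess offsets ended the calls of Nanos2, Crem, Prm3, Mnt, Mxd4, Mga, Mxd3, Tinf2, Nkd1 and Spred1, total counts those of Mxd4, Mga, Mxd3, Tinf2, Spred1 and Acta2, and DESeq2 that of Acta2, all without a change of sign.

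Control KIT-positive cells also differed from control MCAM-medium cells at gene ends of replication, differentiation and ribosome biogenesis genes. Of 57289 peaks, 3267 were higher and 2075 lower in KIT-positive cells. Cdc6 rose by 1.88 ± 0.35 (log2, SE, edgeR adjusted p = 4.23e-04), Kit by 1.42 ± 0.31 (0.00194), and the spermidine synthase gene Srm by 1.40 ± 0.31 (0.00233), while Ccnd2 was at -1.62 ± 0.36 (0.00269) and the ribosome biogenesis gene Pes1 at -1.64 ± 0.34 (0.00144). With camera, replication (14 higher, 0 lower, of 27; adjusted p = 7.84e-08, adjusted p = 0.249 with an estimated correlation), differentiating (5 and 0 of 16; 0.0107, adjusted p = 0.211 with an estimated correlation) and MYC target lists (10 and 1 of 45; 0.00335, adjusted p = 0.496 with an estimated correlation) passed. Adjusted over the list alone these were 20 and 0, 6 and 0, and 14 and 1. With loess offsets 7 replication genes and 5 MYC targets were higher, and the median log2 fold change of the MYC targets went from 0.59 to 0.22. The split was 2347 higher and 3016 lower with total counts (43.8% against 61.2% higher; median log2 fold change -0.20 in place of -0.04) and 2315 higher and 2401 lower with loess offsets (49.1%). The count was 1579 without control MCAM-medium replicate 1, 2814 without MCAM-medium replicate 2 and 2573 without KIT-positive replicate 3. Without MCAM-medium replicate 1 the calls of Ccnd2 and Srm were lost (edgeR adjusted p 0.174 and 0.0574), and without KIT-positive replicate 1 that of the differentiating list (camera adjusted p 0.0538).

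Control MCAM-medium and MCAM-high cells were not told apart as labelled. With edgeR 0 of 57289 peaks passed, with 932 at an unadjusted p under 0.05, and DESeq2 also called 0 (925 at an unadjusted p under 0.05). No list passed with camera (lowest adjusted p 0.102, for the GDNF, FGF and MAPK response). The libraries within these 2 groups did not stand together. On an axis of the 500 peaks that best separated the populations in the deleted libraries alone, built after the data had been seen, deleted MCAM-high libraries scored 1.98 to 2.10 and deleted MCAM-medium libraries 3.78 to 4.03 (mean signed log2 CPM). Control MCAM-high replicates 2 and 3 scored 2.38 each and replicate 1 scored 3.93, whereas control MCAM-medium replicate 1 scored 2.37 and replicate 2 scored 3.91. Without MCAM-high replicate 1 and MCAM-medium replicate 1, 192 peaks were higher and 7 lower in MCAM-medium cells, and with these 2 labels exchanged 1399 and 106. KIT-positive against MCAM-medium cells then gave 1956 and 6761 peaks in place of 5342, and KIT-positive against MCAM-high cells 9515 and 12888 in place of 9024. With the labels exchanged, deleted and control cells differed at 37 peaks in MCAM-high, 31 in MCAM-medium and 7 in KIT-positive cells and 125 in the mean.

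**Figure D4:**
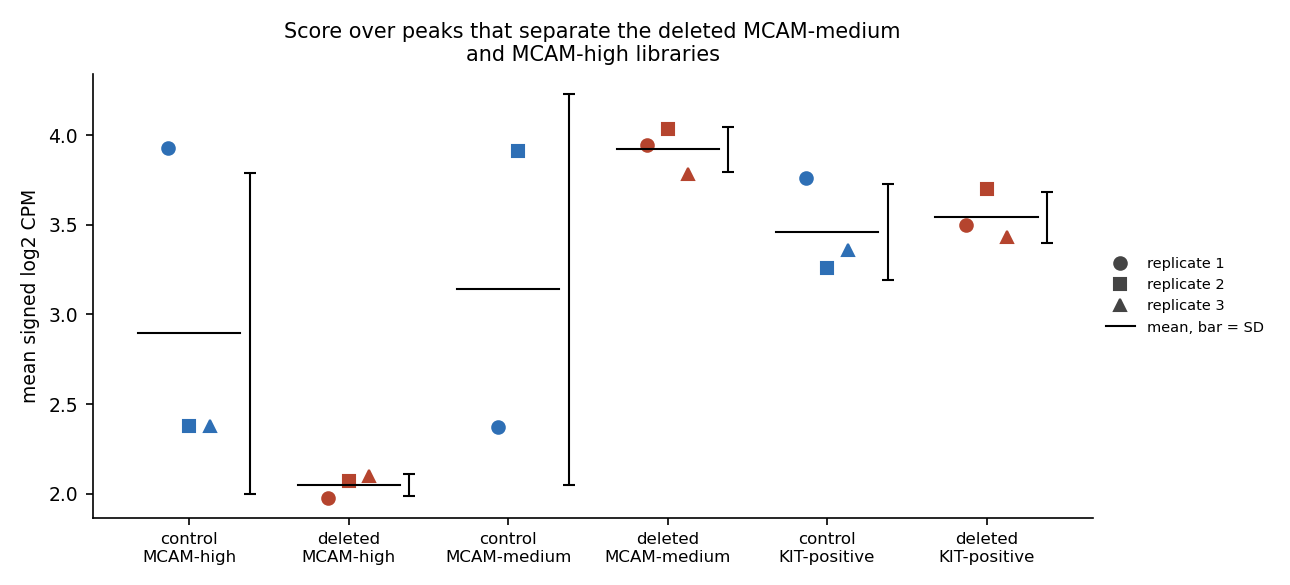
Mean signed log2 CPM over 500 peaks chosen in the deleted libraries (y axis) in the 6 spermatogonial groups (x axis); each point is 1 library, with 1 marker shape per replicate number. Control MCAM-high replicate 1 (3.93) lies with the deleted MCAM-medium libraries (3.78 to 4.03), and control MCAM-medium replicate 1 (2.37) near the other control MCAM-high libraries (2.38).

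Later germ cells differed from control KIT-positive spermatogonia at more called peaks than the spermatogonial populations did from each other. The counts come from separate fits with other libraries, group sizes and tested peaks, so they are not strictly alike. Gene-end peaks of spermiogenesis genes opened: Hils1, a spermatid linker histone, rose by 5.11 ± 0.52 on the log2 scale (SE, edgeR adjusted p = 3.63e-12), Smcp, a sperm mitochondrial protein gene, by 5.06 ± 0.57, Odf1, an outer dense fibre gene, by 4.68 ± 0.49, and Acr, the acrosin gene, by 3.99 ± 0.43. Peaks fell at Sox3 (-3.56 ± 0.33) and Dusp6 (-3.43 ± 0.30) of the undifferentiated list, and at Dmrt1 (-2.82 ± 0.26) and Stra8 (-2.82 ± 0.34) of the differentiating list. These had the smallest p of their lists, and tests of the lists as such are given below. The meiotic gene set was mixed: Pgk2 (2.79 ± 0.40) and Hormad1 (2.40 ± 0.39) rose, and Rad21l (-1.65 ± 0.21) fell. The Terc peak fell by 3.95 (SE 0.30) and the Tert peak by 1.68 (SE 0.36, edgeR adjusted p = 8.11e-05).

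In all, 38026 of 73134 peaks (52.0%) passed, 21345 higher and 16681 lower in later germ cells. DESeq2 size factors gave 24160 higher and 13930 lower and moved the median log2 fold change of all peaks from 0.12 to 0.31, and loess offsets gave 15599 higher and 16452 lower. Gene ends held 26.1% of the higher and 34.1% of the lower sites, against 29.8% of those tested (Fisher's exact test, odds ratios 0.776, 95% interval 0.749 to 0.805, and 1.30, 1.25 to 1.34, with adjusted p = 3.27e-44 and 3.49e-42 over 20 tests). Here too the test counts peaks as independent and does not measure the spread between libraries. Peaks at the ends of the lncRNA genes 4930434J06Rik (chromosome 14, 71856197 to 71856858; 53.3 ± 10.8 CPM, SD, n = 5) and 4933402J10Rik (chromosome 5, 59985803 to 59986277; 49.4 ± 5.88 CPM) had 0 counts in KIT-positive cells and were at least 68.0-fold and 63.0-fold higher. Peaks in Pknox2, Dpysl3, Nuggc, Trdmt1 and Agbl4 and at the ends of St8sia3 and Med10 also had 0 counts there and were at least 53.6-, 52.6-, 52.5-, 48.6-, 45.2-, 47.3- and 45.9-fold higher. The libraries of the 2 groups also differed in kind. Of all peaks, 16.1 ± 3.62% had 0 counts in a KIT-positive library (SD, n = 3) and 4.99 ± 1.76% in a later one (n = 5). Even counts made up 50.7 to 73.9% and 49.3 to 49.9%. What part of the called changes follows from this was not tested. Among the lower sites, the gene-end peak of Hdac6 (X, 7947603 to 7948393) fell from 110 ± 34.1 (n = 3) to 3.12 ± 1.64 CPM (n = 5), the Rcan3 peak from 59.4 ± 23.5 to 1.03 ± 1.29 CPM, and peaks in Syp, Trim71 and Greb1 fell by 5.12, 4.94 and 4.94 on the log2 scale. The stage, the Tert allele and the animals changed together in this comparison, because the later cells carried a Tert tdTomato allele and their library names share 1 animal-like prefix. A day after tamoxifen was given for the spermatogonia only, so the treatment may have changed with them.

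With camera, spermiogenesis rose as a list (22 higher and 1 lower of 25, the same adjusted over the list alone; adjusted p = 3.00e-14, adjusted p = 0.00347 with an estimated correlation), as did meiosis (16 and 6 of 35, 16 and 7 adjusted over the list alone; adjusted p = 0.0425, adjusted p = 0.563 with an estimated correlation). Genes of undifferentiated (1 and 14 of 31; adjusted p = 0.00359) and differentiating spermatogonia (1 and 10 of 16; adjusted p = 0.0233) fell, each with adjusted p = 0.0832 with an estimated correlation. The MYC family (0 and 8 of 11; adjusted p = 0.0143) and WNT targets (0 and 8 of 12; adjusted p = 0.0450) fell, each with adjusted p = 0.205 with an estimated correlation; Mycn was at -2.64 ± 0.48 (SE) and Lgr5 at -1.42 ± 0.31. The meiosis call was lost without KIT-positive replicate 1 or 2 (highest camera adjusted p 0.0587) and that of WNT targets without KIT-positive replicate 2 or later replicate 1 (0.0881). Lists that did not pass were MYC targets (5 and 12 of 45), p53 (6 and 11 of 27), telomeres (4 and 7 of 21), GDNF, FGF and MAPK (3 and 8 of 21), replication (1 and 14 of 27), Sertoli (0 and 4 of 9), Leydig (0 and 2 of 2), immune (0 and 1 of 2), and peritubular or endothelial markers (2 and 6 of 10). Among these, Hk2 was at -3.05 ± 0.24, Ncl at -2.03 ± 0.18, Mcm2 at -1.72 ± 0.26, Trp73 at -3.61 ± 0.41 and Dkc1 at -2.62 ± 0.41, each of which passed, whereas Gar1 rose by 1.33 ± 0.25. With DESeq2 size factors and with loess offsets 9 MYC targets were higher, and 6 and 8 replication genes lower. Of the list genes followed in fits without 1 library, only Inhbb (Sertoli) and Lhcgr (Leydig) lost their calls: without KIT-positive replicate 2 or 3, or later replicate 1 or 2, and for Inhbb also without later replicate 5 (highest edgeR adjusted p 0.126 and 0.0726).

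The share of counts on the sex chromosomes was compared between groups, and no share passed the adjusted threshold. X held 2.25 ± 0.219% of counts in control MCAM-high cells (SD, n = 3), 1.56 ± 0.107% in KIT-positive cells (n = 3; exact permutation test, two-sided p = 0.1, the smallest this design allows, adjusted p = 0.167 over 15 tests) and 0.626 ± 0.13% in later germ cells (n = 5; p = 0.0179 against KIT-positive cells, the smallest it allows, adjusted p = 0.0893). Y held 0.0493 ± 0.00825% in control and 0.0822 ± 0.00708% in deleted MCAM-high cells (exact permutation test p = 0.1, adjusted p = 0.167), and 0.108 ± 0.0121% and 0.112 ± 0.0184% in KIT-positive cells (p = 0.9, adjusted p = 0.9). In MCAM-medium cells Y held 0.0472 ± 0.00651% (n = 2) in control and 0.0900 ± 0.00702% (n = 3) in deleted cells, and X 2.18 ± 0.148% and 1.92 ± 0.0702% (exact permutation test p = 0.1 for each, the smallest this design allows, adjusted p = 0.167). After deletion X held 2.10 ± 0.102% in MCAM-high and 1.60 ± 0.0140% in KIT-positive cells (exact p = 0.300 and 0.9 against the controls, adjusted p = 0.375 and 0.9). The stretch described above held most of the higher Y share: Y peaks outside it had 486 ± 84.1 CPM in control and 437 ± 37.4 CPM in deleted MCAM-high cells, and 466 ± 66.1 and 579 ± 78.7 CPM in MCAM-medium cells, scaled to total counts. Only the comparison with later cells could reach an unadjusted p under 0.05.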

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

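The test of shares on unplaced contigs was added to the share comparisons after the data were seen. Of 33 values tested for a library far from the others among the 5 later germ cell libraries, 3 stood out, and chance gives about 1 in 20. The spermatogonial groups, with fewer libraries each, were not tested in this way. Later germ cell replicate 1 had 3358377 counts, where the nearest of the 4 others had 1946165 and the lowest 1433230. Later germ cell replicate 5 had 1.54 CPM in a peak inside Asph (chromosome 4, 9664606 to 9664892) and 2.06 CPM in a peak inside Myom3 (chromosome 4, 135790519 to 135790976), where the 4 others had 0; beside 4 values of 0 any nonzero value stands out, and 1.54 CPM is 3 counts in that library, scaled to its total.

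The share of counts on unplaced contigs was examined after the data, including the called peaks on 1 such contig, had been seen, so its p-values are no separate evidence for a difference there. The share was 0.415 ± 0.0435% in deleted and 0.330 ± 0.0254% in control MCAM-high cells (SD, n = 3 each), and 0.312 ± 0.0351% and 0.361 ± 0.0419% in KIT-positive cells, neither of which passed alone (exact permutation test, adjusted p = 0.167 and 0.273 over 15 tests). In MCAM-medium cells it was 0.372 ± 0.0383% (n = 3) and 0.315 ± 0.0254% (n = 2; adjusted p = 0.273). The effect of deletion in KIT-positive minus that in MCAM-high cells was -0.134 percentage points (genotype permuted within both populations, 400 permutations, p = 0.015, adjusted p = 0.045 over 3 shares). These permutations moved libraries singly; with libraries of 1 number kept together, as their names would have it, 20 assignments remained and p was 0.1, the smallest they allow. For X and Y the differences were 0.192 and -0.0283 (adjusted p = 0.265 and 0.21).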

How the results depend on the processing

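Settings that leave out X, Y and unplaced contigs, that leave out or exchange the 2 control libraries named below, or that leave out the libraries numbered 1 were chosen after the data were seen, as were all fits of deleted populations. Of the values for counts, lists, shares and the relation across peaks under settings other than the omission of 1 library, 153 stayed and 49 moved. A count stayed if within 1.5 times the reported one, a share or correlation if within 1 SD (between libraries, or between fits without 1 library), and an odds ratio if on the same side of the threshold. Of the values for single peaks, 2073 kept direction and side of the threshold, 95 lost their call, 13 gained one and 4 changed sign. In counts simulated at the depth, spread and number of these libraries most 2-fold changes were missed, and what depth alone limits was not separated. For each changed value below the cause was not tested, except that omitted chromosomes or libraries leave fewer peaks or samples.

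TERT deletion in MCAM-high cells (28 peaks) gave 101 with no filter (70 higher and 31 lower), 15 with glmTreat, 15 without X and Y and 3 without X, Y and unplaced contigs. In MCAM-medium cells (5) it gave 3 with loess offsets, 18 with no filter, 3 with at least 30 counts in at least 2 libraries, 3 with glmTreat, 0 without X and Y (edgeR, 2339 at an unadjusted p under 0.05), 0 without X, Y and unplaced contigs (2317), 12 with only the groups compared and 31 with exchanged labels; DESeq2 gave 4. In KIT-positive cells (2) it gave 8 with no filter, 1 with at least 30 counts in at least 2 libraries, 1 with DESeq2, 0 with glmTreat, 1 without X and Y, 1 without X, Y and unplaced contigs, 1 with only the groups compared, 4 without MCAM-high replicate 1 and MCAM-medium replicate 1 of the controls, and 7 with their labels exchanged. The mean (71) gave 159 with no filter, 43 with at least 30 counts in at least 2 libraries, 41 with glmTreat, 33 without X and Y, 24 without X, Y and unplaced contigs and 125 with exchanged labels. The difference of the deletion effect (0) gave 5 with no filter for MCAM-medium minus MCAM-high and 1 with exchanged labels for KIT-positive minus MCAM-medium.

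Control KIT-positive minus MCAM-high cells (9024) gave 4673 with glmTreat. KIT-positive minus MCAM-medium (5342) gave 2460 with glmTreat, 2805 with only the groups compared and 1956 without those 2 controls. MCAM-medium minus MCAM-high (0) gave 199 without those 2 controls and 1505 with exchanged labels. Deleted KIT-positive minus MCAM-high (7874) gave 3884 with glmTreat. Its split of 68.4% higher became 46.3% (3576 higher and 4154 lower) with total counts, where the median log2 fold change went from -0.05 to -0.28. Deleted MCAM-medium minus MCAM-high (8) gave 5 with total counts, 407 with no filter, 2 with glmTreat, 505 with only the groups compared, 493 without those 2 controls and 631 with exchanged labels. Later germ cells (38026) gave 20004 with at least 30 counts in at least 2 libraries. Of the differentiation lists (7 past the threshold), 0 passed with an estimated correlation and 15 with fry; for deletion 0 passed in each setting. The relation across peaks (0.150) was 0.201 without those 2 controls and 0.213 with exchanged labels.

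With a replicate block the counts were 22 for deletion in MCAM-high cells, 57 for the mean, 6520 for KIT-positive minus MCAM-high, 2172 for KIT-positive minus MCAM-medium, 5975 for deleted KIT-positive minus MCAM-high and 1 for deleted MCAM-medium minus MCAM-high cells. Libraries of the same number and genotype did not deviate together (16 pairs, mean r = -0.0596, highest 0.0531), so these values did not show pairing. The lowest, -0.419 and -0.264, were between control MCAM-high and MCAM-medium libraries numbered 1 and 2. The pair numbered 1 is that with labels in doubt, so the mean is not free of that doubt. Library names carry the number across populations, and pairing stays open. No paired analysis was possible for later germ cells because their numbers follow only the order of deposition. The Fcer1g peak at 171234127, KIT-positive minus MCAM-high, had a log2 fold change of -0.25 with the block against 0.25. The Terc peak at 96413372, beside the one named in the report, had -0.15 in MCAM-high cells without those 2 controls and -0.17 with exchanged labels, against 0.27. The Lhcgr peak at 88791459, KIT-positive minus MCAM-medium, had -0.0315 with total counts against 0.146.

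Leaving out 1 library gave these ranges (an arm left with 1 library is assumed to vary like the other groups). Deletion called 13 to 27 peaks in MCAM-high, 0 to 7 in MCAM-medium and 0 to 2 in KIT-positive cells, and 54 to 80 in the mean. The differences of the effect gave 0 to 0 for KIT-positive minus MCAM-high, 0 to 115 for MCAM-medium minus MCAM-high and 0 to 0 for KIT-positive minus MCAM-medium. Differentiation gave 5054 to 9104, 0 to 0 for MCAM-medium minus MCAM-high, and 1579 to 5921. Deleted populations gave 4878 to 6432 and 0 to 4, and later germ cells 31525 to 36521. Lists past the threshold were 0 to 0 for deletion and 5 to 8 for differentiation, and the relation was 0.0593 to 0.218. Differences in percent of counts on X were -0.268 to -0.0582, -0.359 to -0.150 and -0.0153 to 0.0839 for deletion in MCAM-high, MCAM-medium and KIT-positive cells, -0.813 to -0.603 for KIT-positive minus MCAM-high and -0.994 to -0.895 for later germ cells; on Y they were 0.0285 to 0.0367, 0.0382 to 0.0474, -0.00520 to 0.0131, 0.0538 to 0.0651 and -0.0828 to -0.0720.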

Other observations

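The tests of the 2 control libraries, of the Y stretch and of the Terc peak were chosen after the results were seen, except the exchange of labels for Terc, and the comparisons of deleted populations were added. Within TERT-deleted cells, the step from MCAM-high to KIT-positive cells resembled that in controls: of 57289 peaks, 5382 were higher and 2492 lower in KIT-positive cells, and 4548 were also called in controls. Of these, 3342 were higher and 1203 lower in both, against 519 and 152 for independent lists, and 3 had opposite signs. No library was shared, and r across peaks, which are not independent replicates, was 0.696. The count was 4878 without deleted MCAM-high replicate 2, 5058 without MCAM-high replicate 3 and 5031 without KIT-positive replicate 1.

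Between deleted MCAM-medium and MCAM-high cells 6 peaks were higher and 2 lower; those named here were chosen after their values were seen. A peak inside Fryl, the gene of a FRY-like cytoskeletal protein (chromosome 5, 73047554 to 73048224), had 36.8 ± 9.50 against 4.66 ± 1.17 CPM (SD, n = 3 each; log2 fold change 2.96 ± 0.48 SE, edgeR adjusted p = 0.00815). Peaks inside Akain1, which encodes an inhibitor of protein kinase A anchoring (49.9 ± 5.79 against 7.44 ± 3.11 CPM, edgeR adjusted p = 0.0326), and Kazn, which encodes the junction protein kazrin (33.8 ± 7.10 against 3.93 ± 3.95 CPM, 0.0480), were also higher. None of the 8 calls held in all 6 fits without 1 library, and the count was 0 without MCAM-high replicate 2, MCAM-high replicate 3 or MCAM-medium replicate 3, 1 without MCAM-high replicate 1, 2 without MCAM-medium replicate 2 and 4 without MCAM-medium replicate 1. It was 505 with only these groups fitted, 407 with no filter and 493 without control MCAM-high replicate 1 and MCAM-medium replicate 1. In later germ cells, where title and library name disagreed for 4 of 5 libraries, X held 0.758, 0.766, 0.523, 0.488 and 0.592% of counts in replicates 1 to 5.

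Control MCAM-high replicate 1 and MCAM-medium replicate 1 each stood with the other population on the axis built from deleted libraries. Replicate 1 labelled MCAM-high scored 3.93, above the lowest deleted MCAM-medium library at 3.78 rather than between the populations, which argues against a mixture of both in the sort. Low depth is argued against by the lower of the 2 totals, 2153378, above the median of the 17 libraries, 1466424. A candidate explanation is that the 2 labels were exchanged: the partner scored 2.37, and exchanging them gave 1505 called peaks between the control populations in place of 0. This is a hypothesis found and tested on the same data, no biological explanation was tested for it, and the labels were kept as given in every comparison.

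The 39 peaks of the Y stretch were 35.5-fold higher in deleted than in control libraries with counts pooled, and 53-fold in MCAM-high, 53-fold in MCAM-medium and 12.5-fold in KIT-positive cells (geometric mean 32.8). Depth cannot give this, since CPM is scaled to depth. Y peaks outside the stretch were 1.01-fold by the same geometric mean (0.898, 1.24 and 0.926 in that order), which argues against a change of the whole Y signal. Means of the peaks on the short arm of Y were lower in deleted than in control cells. They were 170 against 218 CPM in MCAM-high, 156 against 212 CPM in MCAM-medium and 100 against 111 CPM in KIT-positive cells. A Y sequence or copy-number difference between the mice of the 2 genotypes and a chromatin response to the deletion both could give the lowest deleted library, at 90.0 CPM, above all controls. These cannot be told apart, because the mice differ along with the genotype and the labels give no mouse line for either. The same limit holds for the peaks called for deletion outside the stretch.

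The fall of the Terc peak in the mean was -1.24 on the log2 scale with the 2 control labels exchanged (edgeR adjusted p = 8.05e-05), which argues against that exchange as its cause. Without the 3 deleted libraries numbered 1 it was -1.07 (edgeR adjusted p = 0.264), fewer libraries being left. Of 9 deleted libraries, 6 lay under every control of their population as labelled. Whether the fall may be a response to the deletion or comes from single libraries cannot be told apart. As labelled, control values spread from 177 to 711 CPM in MCAM-high, 191 to 717 CPM in MCAM-medium and 165 to 343 CPM in KIT-positive cells. The 177 and 717 CPM belong to the 2 libraries whose labels are in doubt, so exchanged labels would narrow the spread within both populations. Deleted libraries also spread widely, and the call was lost without those numbered 1.

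Other splits of the same libraries were tried. With 10 splits of 6 libraries, of which 1 (the real one) reached its own count each time, a share under 0.05 cannot be had: the real split and the highest other gave 28 and 3 peaks for deletion in MCAM-high cells, 2 and 0 in KIT-positive cells, 9024 and 0 for control KIT-positive minus MCAM-high, 7874 and 0 for the same in deleted cells, and 8 and 0 for deleted MCAM-medium minus MCAM-high cells. For the mean deletion effect 1 of 40 splits, the real one, gave as many as 71 (highest other 46), a share under 0.05 if libraries are independent. The other splits were a random sample of those possible, and neighbouring called peaks are not separate sites, so chance is not excluded. The splits moved libraries singly; if libraries of 1 number came from 1 animal, too few splits exist for a share under 0.05. For the difference of the deletion effect between KIT-positive and MCAM-high cells all 40 splits reach the real 0 whatever they hold (highest other 27; edgeR, 2855 at an unadjusted p under 0.05; DESeq2 0), so the splits say nothing of chance there. For later germ cells 1 of 56 splits gave as many as 38026 (highest other 0), a share under 0.05 if libraries are independent. The shared name prefix of the 5 later libraries leaves that open.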
